A study of Mus musculus with 8 samples.

How the data were processed

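The series holds 8 Affymetrix Mouse Genome 430 2.0 arrays in 4 groups of 2: ESC Zfx-flox, ESC Zfx-null, HSC Zfx-flox and HSC Zfx-cko. Per the labels' protocols, ESC RNA went through a single round of linear amplification, while RNA of HSC, sorted from marrow pooled over several littermates, went through an additional round. Marrow was taken 4 days past the end of pI·C treatment. Samples were hybridized in duplicate, per the series' design text, so the arrays of a group may share 1 RNA sample. The deposited values are probe set intensities on a linear scale, made by the authors with GCOS 1.4, per the submitters' processing notes. The summarisation settings are not given in the sources used here. Each deposited column had a mean of 250 after removal of the highest and lowest 2% of probe sets, so the arrays had been scaled to a common target, and no logarithm or centring per gene had been applied. Every value column was assigned to a sample by its label, and 0 columns were without a sample.

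Arrays give no counts, so only the number of arrays and the signal over background limit the precision. The median standard error of a tested gene's log2 change was 0.141 in ESC and 0.139 in HSC. The fold changes are on the scale log2(value + 14.2), where 14.2 is the 25th percentile of all deposited values, which understates the change of dim genes. The deposited scaling was kept because the trimmed means were equal. The 64 control probe sets were left out of all tests. A probe set was tested in a comparison when its mean over the 4 arrays of that cell type reached the 40th percentile, which left 27022 of 45101 probe sets.

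Probe sets were named through the platform annotation: 34945 had 1 gene symbol, 932 several and 9160 none, and only those with 1 symbol were named. Of the former, 34741 matched a gene of the RefSeq table (assembly GRCm38.p6) by identifier, and 0 symbols changed. The 18193 genes were each represented by the probe set with the highest mean log2 value over all arrays, and other probe sets of named genes were looked up. Genes on the lists without such a probe set were not analysed here.

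A single linear model of the 4 group means was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (eBayes with a variance trend, 4 residual degrees of freedom, a median of 4.24 prior ones). Contrasts were Zfx-null minus Zfx-flox in ESC, Zfx-cko minus Zfx-flox in HSC, and the HSC minus the ESC effect. P-values were adjusted by Benjamini and Hochberg per comparison, with a threshold of 0.05. Joint fitting pools the spread over cell types, since a fit of 1 cell type leaves 2 residual degrees of freedom. Overlaps were tested with two-sided Fisher's exact tests over genes tested in both cell types. With 2 arrays per group no comparison of single values by permutation was made, and no outlier test applied to any group.

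Gene lists numbered 34: core pluripotency; endoderm; primitive streak and mesoderm; neuroectoderm and epiblast; trophectoderm; 2-cell and germline; hematopoietic stem cell; lymphoid-primed progenitor; erythroid and megakaryocyte; granulocyte and monocyte; B, T and NK lineage; mast cell and eosinophil; fibroblast and stroma; endothelial; p53 targets; integrated and endoplasmic reticulum stress; immediate early and AP-1; heat shock; oxidative stress and metallothionein; interferon response; apoptosis regulators; S phase; mitosis; G1 regulators; cytosolic ribosomal proteins; ribosome biogenesis; oxidative phosphorylation; glycolysis and hypoxia; cholesterol biosynthesis; imprinted; Y-linked and X-inactivation; Zfx paralogs; JAK-STAT and LIF; and Notch, Wnt and BMP targets. Lists with at least 5 tested members (30 in ESC, 31 in HSC) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. The latter version also refers to the 4 residual degrees of freedom, which raises p whatever the correlation. For core pluripotency in ESC the estimated correlation was −0.0016, below the preset one, yet camera's p rose from 6.36e-10 to 0.00213. A call lost in that version thus does not by itself show that the list's members vary together. Some genes stand on more than 1 list.

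Named genes followed a rule. Zfx came first, then per comparison the 10 genes with the largest fitted change in each direction among those past the threshold whose arrays of the groups did not overlap. Per list, up to 4 members past the threshold with the largest change and up to 2 others with the highest mean could be named, besides 5 genes per direction for the overlap and for the difference between cell types, and Tbx3 and Tcl1 in any case. Exceptions are stated. The groups, tests, lists, this rule and the alternatives were chosen before the data were examined.

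Alternatives changed a single choice at a time: the pseudocount (10th percentile or none), the scaling (quantile normalization within cell types or over all arrays, or median centring within cell types), the filter (none or the 60th percentile), each cell type fitted alone, no variance trend, the replicate number as a block, the mean of all probe sets of a gene, a minimum change of 2-fold, an estimated correlation or fry for the lists, and leaving out each array in turn. The steps were tested on simulated data. Among 27022 simulated probe sets, 48.2%, 70.3% and 85.7% of changes of 1.5-, 2- and 4-fold were recovered for the ESC comparison and 33.3%, 71.4% and 92.4% for the HSC comparison. Unchanged probe sets made up 5 of 144 ESC calls and 6 of 141 HSC calls. Among 12533 simulated HSC genes, a list shifted by 0.3 was called and 0 of 30 random lists were. Each simulated gene varied independently, so this cannot show whether the preset correlation holds for lists of genes that vary together. Far fewer probe sets were changed in the simulation than were called in the data.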

Results

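Gene expression was measured in 2 mouse stem cell types with and without the zinc finger factor Zfx. Embryonic stem cells (ESC), cultured without feeder cells in serum replacement and LIF, carried either a loxP-flanked Zfx gene (Zfx-flox) or a deleted one (Zfx-null). Hematopoietic stem cells (HSC) were Lin− Sca-1+ c-Kit+ marrow cells, a population that holds stem cells and multipotent progenitors. They were sorted after pI·C injection of Zfx-flox mice without Cre or of Mx1-Cre+ conditional knockout mice (Zfx-cko), in which interferon-inducible Cre deletes the gene. Cre was therefore present in the HSC Zfx-cko arrays alone. Each of the 4 groups had 2 arrays, which per the labels may be duplicate hybridizations. P-values therefore measure only the spread between arrays, which may be technical. Each array read a population of cells, so a change within cells was not told apart from a change in their mix. Arrays of 1 group correlated at r = 0.995 to 0.998 across probe sets, against 0.970 to 0.973 between Zfx-null and Zfx-flox ESC, 0.964 to 0.965 between Zfx-cko and Zfx-flox HSC, and 0.765 to 0.791 between cell types. No 2 arrays of a group shared identical values. The median signal per array was 38.4 to 66.5, and 69.4% to 78.9% of probe sets lay above the pseudocount of 14.2.

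Markers followed the labelled cell types. Pou5f1, the core pluripotency factor, gave a signal of 3343 ± 174 (mean ± SD, n = 2, as for all levels) in ESC Zfx-flox and 8.74 ± 3.4 in HSC Zfx-flox, and Nanog gave 2627 ± 98.7 and 1.59 ± 0.394. Cd34, a progenitor surface protein, gave 40.2 ± 3.2 in ESC Zfx-flox and 1075 ± 24.1 in HSC Zfx-flox. The stem cell factor receptor Kit, used in the sort, was at 1046 ± 109.5 and 1148 ± 36.9. The B, T and myeloid markers Cd79a, Cd3e and Itgam lay at 19.8 ± 10.7, 5.7 ± 0.443 and 1.3 ± 0.585 in HSC Zfx-flox. Cell types were not tested against each other, because HSC RNA had an extra amplification round. The Gapdh control probe sets differed between them as well, with a log2 ratio of 5′ to 3′ signal of 0.38 to 0.44 in ESC, −4.18 and −4.25 in HSC Zfx-flox and −4.68 and −4.39 in HSC Zfx-cko. The round cannot be told apart from the cell type.

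Zfx itself was read by 7 probe sets, 4 annotated to Zfx alone and 3 also to the pseudogene Zfa-ps. Probe set 1422249_s_at read 285 and 298 on the ESC Zfx-flox arrays and 1.32 and 0.878 on the Zfx-null arrays, a log2 change of −4.32 ± 0.24 (SE, adjusted p = 4.23e-05). The Zfx-null values lie below the pseudocount, which sets the size of this change. In HSC it was near the floor in both groups, at 7.22 and 0.971 in Zfx-flox and 1.34 and 0.305 in Zfx-cko. It was not tested there and does not check the HSC labels. In ESC the other probe sets went the opposite way or did not pass. The probe set with the highest mean, 1425972_a_at, rose from 290.0 ± 39.5 to 512 ± 49.2 in Zfx-null ESC (log2 change 0.79 ± 0.11, adjusted p = 0.00137). In addition 4 others rose by 1.33 to 1.65, while 1439404_x_at changed by −0.12 (adjusted p = 0.785). In HSC, 1425972_a_at read 696 and 752 in Zfx-flox and 1192 and 1209 in Zfx-cko (log2 change 0.72 ± 0.11, adjusted p = 0.00104). With the mean of all Zfx probe sets, the ESC value was 1.40 and the HSC value 0.26 (adjusted p = 0.141, within 0.000342 to 0.141 over the alternatives). The remaining tested probe sets did not pass in HSC, at −0.49 for 1419565_a_at, 0.05 for 1428046_a_at, 0.10 for 1428047_s_at and −0.00 for 1439404_x_at. Whether these probe sets lie in the deleted part of the gene is not given in the sources used here, so they check nothing about the deletion. The X-linked paralog Zfp711 rose in both cell types, from 26.7 ± 8.88 to 171 ± 28.8 in ESC (log2 change 2.18 ± 0.27, adjusted p = 0.000894) and from 12.3 ± 6.47 to 101 ± 4.95 in HSC (log2 change 2.14 ± 0.27, adjusted p = 0.000408).

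**Figure D1:**
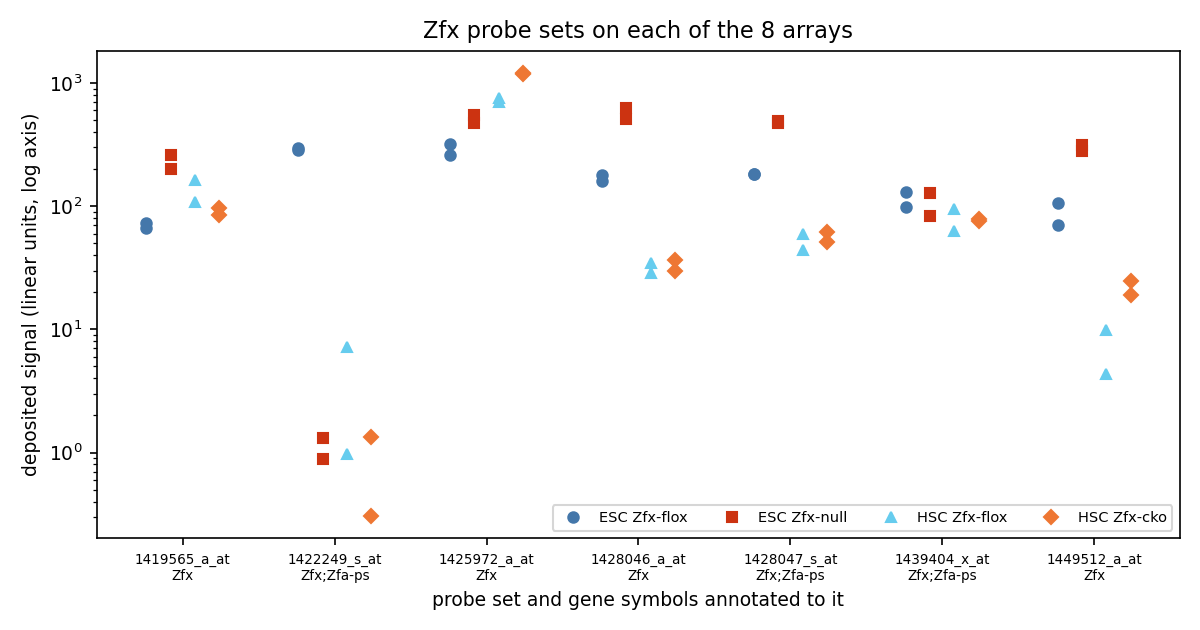
Deposited signal (linear units, log axis) of the 7 Zfx probe sets on each of the 8 arrays, 1 point per array, with the gene symbols annotated to each probe set. Probe set 1422249_s_at is at 285 and 298 in ESC Zfx-flox and at 1.32 and 0.878 in ESC Zfx-null, while 5 other probe sets are higher in Zfx-null ESC.

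The ESC comparison addressed which transcripts differ between Zfx-null and Zfx-flox ESC cultures. Genes of the pluripotency network, of DNA replication and of mitosis were lower in Zfx-null ESC, and immediate early genes were higher. Of the fibroblast and stroma, G1 regulator and imprinted lists 12 of 19, 10 of 21 and 9 of 19 genes rose, but these list calls were lost with an estimated correlation (adjusted p = 0.122, 0.0897 and 0.136). That correlation was 0.11, −0.0065 and 0.0029, so for the G1 and imprinted lists it lay below the preset one. Lefty2, a Nodal antagonist made by pluripotent cells, went from 648 ± 39 to 194 ± 5.27, and the proliferation antigen Mki67 from 3141 ± 134 to 1852 ± 19.3. Gdnf, a neurotrophic factor, went from 9.37 ± 2.87 to 288 ± 4.66, and the AP-1 subunit Fosl2 from 163 ± 2.54 to 801 ± 64.9. Of 12676 genes tested, 3665 passed an adjusted p of 0.05 in limma (28.9%), 1894 higher and 1771 lower in Zfx-null, of which 494 and 172 changed at least 2-fold.

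The 10 largest rises after Gdnf (log2 change 3.69 ± 0.22, adjusted p = 5.07e-05) continued with the small Maf protein Maff (6.06 ± 0.588 to 143 ± 18.2, log2 change 2.95 ± 0.27, adjusted p = 0.000227) and the oxysterol-binding protein homolog Osbpl5 (log2 change 2.71 ± 0.39). Next came the interferon-activated gene Ifi202b (2.63 ± 0.15), the sulfate donor synthase Papss2 (2.59 ± 0.22), the transcription factor Nfil3 (2.44 ± 0.46) and the neuropeptide precursor Vgf (248 ± 41.4 to 1389.7 ± 247, log2 change 2.42 ± 0.20, adjusted p = 0.000151). They were followed by smooth muscle calponin Cnn1 (2.25 ± 0.19), matrix Gla protein Mgp (2.24 ± 0.61) and the pentraxin Ptx3 (2.24 ± 0.23). The largest fitted fall was that of Spesp1, a sperm head protein, from 211 ± 10.2 to 8.74 ± 8.5 (log2 change −3.35 ± 0.28, adjusted p = 0.000171). Gm20767 (−2.58 ± 0.22), AF067061 (−2.43 ± 0.25), BC080696 (−2.39 ± 0.22), Sned1 (−2.11 ± 0.28), the deubiquitinase gene Usp17la (−2.07 ± 0.27), Speer4cos (−2.04 ± 0.27), the zinc finger gene Zfp746 (−2.02 ± 0.24) and the T cell receptor kinase Zap70 (−1.96 ± 0.57) fell too. Cibar1, which acts in cilium formation, went from 658 ± 44.6 to 114 ± 2.09 (log2 change −2.39 ± 0.09, adjusted p = 2.44e-05). Gdnf, Maff and Osbpl5 in Zfx-flox and Spesp1 in Zfx-null lay below the pseudocount, which sets the size and rank of their change. With the pseudocount at the 10th percentile they were at 4.50, 3.91, 3.44 and −4.31. The calls of Mgp (adjusted p = 0.0305) and Zap70 (0.0381) were lost without single arrays. Without ESC Zfx-flox replicate 2, Zfx-null replicate 1, Zfx-null replicate 2 or HSC Zfx-cko replicate 2 the adjusted p of Mgp was 0.149, 0.114, 0.113 and 0.05 (0.0111 to 0.207 over all alternatives). That of Zap70 was 0.125 and 0.143 without ESC Zfx-flox replicate 1 or 2, 0.207 without Zfx-null replicate 2, and 0.0602 and 0.06 without HSC Zfx-flox replicate 1 or 2 (0.0155 to 0.207 over all alternatives). The log2 change of Mgp was 1.31 without ESC Zfx-flox replicate 2. That of Zap70 was −1.25 without ESC Zfx-null replicate 2 and −0.53 with the mean of all its probe sets. The other 2 tested probe sets of Zap70 did not pass, at −0.08 and 0.44.

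Among 31 tested core pluripotency genes, 18 fell and none rose (21 fell adjusted over the list alone, median log2 change −0.64, camera adjusted p = 9.54e-09). The fallers with the largest change were Lefty2 (log2 change −1.67 ± 0.24, adjusted p = 0.00176), the orphan receptor Nr0b1 (−1.37 ± 0.19), the Nodal co-receptor Tdgf1 (−1.19 ± 0.13) and Prdm14 (−1.16 ± 0.23). Tbx3, a T-box factor linked to ESC self-renewal, went from 521 ± 11.8 to 256 ± 32.5 (log2 change −0.99 ± 0.22, adjusted p = 0.0131), and 2 further Tbx3 probe sets fell as well. Its adjusted p was 0.0681, 0.076 and 0.0866 without ESC Zfx-flox replicate 1, Zfx-flox replicate 2 or Zfx-null replicate 1 (0.00367 to 0.0866 over all alternatives). Tcl1, an Akt co-activator, gave 354 ± 20 to 175 ± 21.5 and did not pass (log2 change −0.96 ± 0.32, adjusted p = 0.0608), nor did Dppa4 (log2 change −0.54 ± 0.18, adjusted p = 0.0681) or Zfp42 (log2 change −0.49 ± 0.23, adjusted p = 0.17). Pou5f1 fell by 1.01 ± 0.26 (adjusted p = 0.0237) and Nanog by 0.71 ± 0.11 (adjusted p = 0.00295), whereas Sox2 did not pass (log2 change −0.26 ± 0.17, adjusted p = 0.313). The adjusted p of Pou5f1 was 0.0895, 0.116 and 0.149 without ESC Zfx-flox replicate 1, Zfx-flox replicate 2 or Zfx-null replicate 1 (0.00538 to 0.326 over all alternatives), and that of Nanog 0.122 without a pseudocount, its highest. Pou5f1, Nanog and Sox2 were chosen after their values were seen. The standard errors pool the spread over both cell types, so they also hold that of HSC. In ESC Zfp42 went from 3274 ± 15.6 to 2325 ± 121 and Sox2 from 3227 ± 111 to 2696 ± 110. In HSC Zfx-flox and Zfx-cko both lay near the floor, Zfp42 at 9.15 ± 4.46 and 17.8 ± 12, Sox2 at 2.17 ± 1.56 and 4.23 ± 4.57. Their failure to pass therefore does not rest on the ESC spread alone.

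Replication and mitosis genes fell in Zfx-null ESC. Of 27 tested S phase and replication genes, 18 fell and none rose (20 fell adjusted over the list alone, median −0.35, adjusted p = 6.53e-07). The most changed were cyclin E1, Ccne1 (1991 ± 377 to 1072 ± 238, log2 change −0.89 ± 0.16, adjusted p = 0.00563), and the GINS helicase subunits Gins2 (−0.74 ± 0.13) and Gins1 (−0.74 ± 0.13). Of 28 mitosis genes, 21 fell and none rose (23 fell adjusted over the list alone, median −0.46, adjusted p = 3.3e-10). The centromeric histone Cenpa (−0.76 ± 0.06), Mki67 (log2 change −0.76 ± 0.06, adjusted p = 0.000133), the checkpoint kinase Bub1b (−0.72 ± 0.08) and the ubiquitin-conjugating enzyme Ube2c (−0.68 ± 0.07) changed most. Of 21 cyclin-dependent kinase inhibitors and G1 regulators, 10 rose and none fell (12 rose and 1 fell adjusted over the list alone, median 0.29, adjusted p = 0.000705, adjusted p = 0.0897 with an estimated correlation). They included the antiproliferative gene Btg1 (1.07 ± 0.07) but also Ccnd2 (1.04 ± 0.06) and Cdk6 (0.94 ± 0.05), which drive G1 progression.

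Of 32 immediate early and AP-1 genes, 16 rose and 2 fell (19 and 3 adjusted over the list alone, median 0.44, adjusted p = 1.86e-06). Maff, Fosl2 (log2 change 2.20 ± 0.10, adjusted p = 3.37e-05), the stress-inducible gene Ier3 (537 ± 4.74 to 1793 ± 10, 1.71 ± 0.08) and the ERK phosphatase Dusp5 (228 ± 37.9 to 666 ± 0.00636) changed most. Of 19 fibroblast and stroma genes, 12 rose and none fell (13 rose adjusted over the list alone, median 0.75, adjusted p = 7.42e-07, adjusted p = 0.122 with an estimated correlation). The calcium-binding protein S100a4 went from 139.6 ± 29 to 398 ± 21.6 (1.43 ± 0.15), the collagen cross-linking enzyme Lox from 969 ± 63.8 to 2629 ± 63.6 (1.43 ± 0.17). The matricellular protein Ccn1 went from 2276 ± 221 to 5883 ± 173 (1.37 ± 0.21) and collagen III, Col3a1, from 2620.3 ± 13 to 6151 ± 179 (1.23 ± 0.10). Lox, Ccn1 and Col3a1 lay above the arrays' 90th percentile (829 and 825) already in Zfx-flox ESC. Whether they rose in all cells, or in a larger share of cells that express them, was not tested. Among 19 imprinted genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.0104, adjusted p = 0.136 with an estimated correlation). Among them were Nnat (1.81 ± 0.23), Plagl1 (1.67 ± 0.31), Sgce (1.47 ± 0.12) and the growth factor receptor adaptor Grb10 (0.89 ± 0.07).

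Some genes of protein synthesis and respiration were slightly lower in Zfx-null ESC. Among 31 cytosolic ribosomal protein genes, 9 fell and none rose (11 fell adjusted over the list alone, median −0.17, adjusted p = 3.02e-05, adjusted p = 0.467 with an estimated correlation). The median was −0.055 and −0.060 with quantile normalization within cell types and over all arrays. Rpl8 was 1 of the 9 (log2 change −0.35 ± 0.06, adjusted p = 0.00402). Of 25 ribosome biogenesis genes, 7 fell and none rose, also adjusted over the list alone (median −0.19, adjusted p = 0.0011, adjusted p = 0.0941 with an estimated correlation). They included the snoRNP core protein Nop56 (−0.48 ± 0.06). Of 28 oxidative phosphorylation genes, 14 fell and none rose (16 fell adjusted over the list alone, median −0.21, adjusted p = 3.02e-05, adjusted p = 0.187 with an estimated correlation). These included Cox8a (log2 change −0.39 ± 0.06, adjusted p = 0.0021). The lists whose calls held with an estimated correlation were core pluripotency, S phase, mitosis and immediate early genes, each with an adjusted p of 0.0399.

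The remaining ESC lists did not pass as lists. Where counts are given once, those adjusted over the list alone were the same. Of 16 endoderm genes 6 rose and 1 fell (adjusted p = 0.0542). They included the endocytic adaptor Dab2 (406 ± 9.46 to 1139.9 ± 46.9, 1.46 ± 0.14), the collagen chaperone Serpinh1 (1.11 ± 0.11) and collagen IV, Col4a1 (0.96 ± 0.12). Of 16 neuroectoderm and epiblast genes 3 rose and 4 fell (adjusted p = 0.965), with the neural factor Sox11 at 1.55 ± 0.12 and Gbx2 at −1.14 ± 0.15. Primitive streak and mesoderm had 2 higher and 2 lower of 11 (0.729, Hoxb1 −1.25 ± 0.23), and trophectoderm 1 higher of 14 (0.729). The 2-cell and germline list had 2 lower of 9 (0.21, Zfp352 −1.53 ± 0.25). Of 25 hematopoietic stem cell genes 8 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.138), with the endothelial protein C receptor Procr at 1.62 ± 0.11 and Runx1 at 1.29 ± 0.12. Erythroid and megakaryocyte genes had 1 higher and 2 lower of 13 (1 and 3 adjusted over the list alone, adjusted p = 0.729). Granulocyte and monocyte genes had 2 higher of 7 (0.428) and endothelial genes 2 higher and 3 lower of 10 (2 and 6 adjusted over the list alone, 0.285). The lymphoid-primed list with 4 tested genes (1 higher, 1 higher and 1 lower adjusted over the list alone), the B, T and NK list with 3 (0 past), the paralog list with Zfp711 alone and the mast cell list with 0 were too short for a list test.

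Of 26 p53 targets 5 rose and 2 fell in Zfx-null ESC (8 and 4 adjusted over the list alone, adjusted p = 0.191), including the cyclin-dependent kinase inhibitor Cdkn1a (0.89 ± 0.11). Integrated and endoplasmic reticulum stress genes had 2 higher and 3 lower of 30 (1 and 3 adjusted over the list alone, adjusted p = 0.663, Nupr1 1.57 ± 0.20). Heat shock genes had 2 lower of 16 (0.285) and oxidative stress and metallothionein genes 4 higher and 5 lower of 19 (4 and 6 adjusted over the list alone, 0.304), with metallothionein Mt1 at 1.39 ± 0.09. Of 19 interferon response genes 6 rose and 2 fell (adjusted p = 0.0697), including the guanylate-binding protein Gbp2 (1.35 ± 0.08). Apoptosis regulators had 5 higher and 2 lower of 24 (6 and 3 adjusted over the list alone, 0.428). Glycolysis and hypoxia genes had 2 and 4 of 24 (0.728), and cholesterol biosynthesis genes 2 and 8 of 18 (2 and 9 adjusted over the list alone, 0.245). JAK-STAT and LIF signalling genes had 3 higher and 4 lower of 14 (0.883), with the kinase Jak2 at 1.39 ± 0.08. Notch, Wnt and BMP targets had 4 and 1 of 15 (0.123), and Y-linked and X-inactivation genes 1 lower of 5 (0.516). In the erythroid, neuroectoderm and JAK-STAT lists the median, the mean and the test did not share a sign.

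Without a pseudocount the adjusted p reached its highest value and passed 0.05 for Speer4cos (0.0864), Lefty2 (0.111), Nr0b1 (0.114), Tdgf1 (0.201), Nnat (0.106) and Plagl1 (0.196). It did so for Rpl8 (0.0726) and Cox8a (0.0529) without a variance trend, and for Prdm14 without ESC Zfx-flox replicate 2 (0.0596) or Zfx-null replicate 2 (0.0514). Without a pseudocount the log2 changes of Speer4cos, Lefty2, Nr0b1, Tdgf1, Nnat and Plagl1 did not become smaller, at −2.36, −1.74, −1.44, −1.19, 1.83 and 1.82. The joint fit pools the spread over both cell types, so these p-values also hold the HSC spread. The 1771 lower genes were 933 without a variance trend, 1162 with median centring, 1046 without ESC Zfx-flox replicate 1 and 1112 without ESC Zfx-flox replicate 2. With the mean of all probe sets of a gene, the log2 changes of Fosl2 (1.25), Ptx3 (1.18), Sgce (0.79), Runx1 (0.67), Gins1 (−0.46) and Bub1b (−0.36) were smaller by over 1.5 times and still passed. Further tested probe sets of Bub1b, Fosl2, Btg1, Cdkn1a, Grb10, Col4a1, Runx1 and Cox8a did not all pass, and none passed in the opposite direction.

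The HSC comparison addressed which transcripts change when Zfx is lost from hematopoietic stem and progenitor cells. Stem cell genes and immediate early genes were higher in Zfx-cko, and ribosome biogenesis and replication genes were lower. Lymphoid-primed progenitor genes were higher and erythroid and heat shock genes lower too, but these list calls were lost with an estimated correlation (adjusted p = 0.0736 each). For the lymphoid-primed and erythroid lists that correlation lay below the preset one (−0.045 and −0.016), so it is not what raised their p. For heat shock it lay above (0.052). Meis1, a homeodomain factor of stem cells, went from 595 ± 22.4 to 3243 ± 88.2, the terminal transferase Dntt of lymphoid precursors from 511 ± 68 to 3222 ± 325 and the AP-1 subunit Fos from 569.7 ± 39.9 to 4471 ± 639. The erythroid membrane protein Ermap went from 6288 ± 79.5 to 541 ± 14.2 and the inducible heat shock protein Hspa1b from 3654 ± 253 to 283 ± 20.2. Of 12533 genes tested, 5199 passed (41.5%), 2773 higher and 2426 lower in Zfx-cko, of which 857 and 439 changed at least 2-fold. The balance turned with the scaling, to 2442 higher and 2731 lower with quantile normalization within cell types, 2293 and 2521 over all arrays, and 2056 and 2650 with median centring. The 18S ribosomal RNA control probe sets were lower in Zfx-cko, at −0.55 (3′), −0.13 (5′) and −1.20 (middle) on the log2 scale.

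Rnase4, a secreted ribonuclease, had the largest rise, from 92.7 ± 7.79 to 859.8 ± 39.3 (log2 change 3.03 ± 0.09, adjusted p = 1.35e-06). It was followed by Fos (log2 change 2.94 ± 0.11, adjusted p = 2.06e-06), the protein kinase C substrate Marcks (2.76 ± 0.06), Dusp5 (2.70 ± 0.14) and Asb4 (2.70 ± 0.31), and then by the adhesion molecule Chl1 (2.70 ± 0.26), Fgf13 (2.69 ± 0.17), the class II-like antigen presentation gene H2-Ob (2.67 ± 0.18), the platelet integrin Itgb3 (2.66 ± 0.26) and Dntt (2.63 ± 0.19). The deepest falls were those of Tlcd4 (1253 ± 157 to 47.8 ± 12.5, log2 change −4.36 ± 0.35, adjusted p = 4.58e-05) and the red cell Rh-associated glycoprotein Rhag (1672 ± 208 to 95.2 ± 41.9, log2 change −4.00 ± 0.32, adjusted p = 4.63e-05). Hspa1b (−3.63 ± 0.12), the claudin Cldn13 (−3.51 ± 0.41), Ermap (−3.51 ± 0.16), lamin A/C, Lmna (−3.48 ± 0.13), sphingosine kinase Sphk1 (−3.33 ± 0.14), Cachd1 (−3.32 ± 0.10), Hspa1a (−3.25 ± 0.18) and Cibar1 (−3.20 ± 0.09) completed the 10 largest falls.

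Of 35 hematopoietic stem cell genes, 20 rose and 3 fell (21 and 3 adjusted over the list alone, median 0.65, adjusted p = 1.06e-05). The list was led by Procr (306 ± 40.3 to 1751 ± 53.1, log2 change 2.47 ± 0.11, adjusted p = 4.09e-06), Meis1 (2.42 ± 0.10), Mecom (1.75 ± 0.25) and Cd34 (1.62 ± 0.09). Of 12 multipotent and lymphoid-primed progenitor genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.27, adjusted p = 0.000656, adjusted p = 0.0736 with an estimated correlation). Besides Dntt these were led by the chemokine receptor Ccr9 (2.46 ± 0.25), the cytokine receptor Flt3 (328 ± 54.9 to 1829 ± 102, 2.44 ± 0.13) and the chromatin organiser Satb1 (1.64 ± 0.11). Of 17 erythroid and megakaryocyte genes, 12 fell and 3 rose, also adjusted over the list alone (median −1.32, adjusted p = 0.000656, adjusted p = 0.0736 with an estimated correlation). Besides Ermap and Sphk1 the fallers included the Rh antigen Rhd (−2.84 ± 0.12) and the erythroid transcription factor Klf1 (1924 ± 71.2 to 324 ± 8.43, −2.52 ± 0.20). The 3 that rose, named after their values were seen, are megakaryocyte or platelet genes, Gp9 (2.35 ± 0.29), Pf4 (1.85 ± 0.18) and Itga2b (0.95 ± 0.14). The Gapdh and beta-actin 5′ to 3′ log2 ratios differed between Zfx-cko and Zfx-flox by −0.32 and −0.14, with a larger SD within groups of 0.21 and 0.11.

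Of 33 immediate early and AP-1 genes, 24 rose and 1 fell in Zfx-cko HSC (26 and 1 adjusted over the list alone, median 1.23, adjusted p = 7.71e-10). Jun (2.46 ± 0.17) and Ier3 (2.33 ± 0.08) changed most next to Fos and Dusp5. JAK-STAT and LIF signalling genes rose in 8 cases of 13 and fell in 1 (9 and 1 adjusted over the list alone, median 0.48, adjusted p = 0.00356, adjusted p = 0.165 with an estimated correlation). They included Klf4 (1.90 ± 0.13), the feedback inhibitor Socs3 (1.48 ± 0.22), Gab1 (1.06 ± 0.07) and the kinase Pim1 (1.02 ± 0.10). Heat shock genes fell in 13 cases of 16 and none rose, also adjusted over the list alone (median −0.60, adjusted p = 5.51e-07, adjusted p = 0.0736 with an estimated correlation). Besides Hspa1b and Hspa1a the chaperones Hsph1 (3473 ± 81.4 to 1451 ± 48.8, −1.25 ± 0.06) and Hspd1 (−0.92 ± 0.12) fell most.

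Replication and ribosome production genes were lower in Zfx-cko HSC. Of 27 S phase and replication genes, 17 fell and none rose (20 fell and 1 rose adjusted over the list alone, median −0.44, adjusted p = 7.23e-07). Among the most changed were Ccne1 (4258 ± 415 to 709.6 ± 1.81, log2 change −2.56 ± 0.16, adjusted p = 1.44e-05), Orc1 (−1.08 ± 0.10) and Cdc6 (−0.95 ± 0.08). Of 25 ribosome biogenesis genes, 21 fell and none rose, also adjusted over the list alone (median −0.61, adjusted p = 1.44e-09). The nucleolar proteins Nolc1 (1845 ± 80.2 to 709.9 ± 28.9, −1.36 ± 0.10), Bysl (−1.24 ± 0.08), Ddx21 (−0.92 ± 0.07) and Mybbp1a (−0.89 ± 0.08) changed most. Oxidative phosphorylation genes fell in 13 cases of 28 and none rose (14 fell adjusted over the list alone, median −0.17, adjusted p = 3.84e-05, adjusted p = 0.177 with an estimated correlation). The median was −0.27 with median centring. Ndufs1 (−0.86 ± 0.07) and Uqcrfs1 (−0.80 ± 0.07) were among the fallers. Of 19 cyclin-dependent kinase inhibitors and G1 regulators, 9 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.0268, adjusted p = 0.165 with an estimated correlation). The median was 0.14 with median centring. The risers included Ccng2 (1.58 ± 0.07), cyclin D1, Ccnd1 (1.24 ± 0.07), Cdkn2d (1.12 ± 0.16) and Cdkn1a (1.11 ± 0.11). Among 31 cytosolic ribosomal protein genes, 3 rose and 1 fell (2 rose and 0 fell adjusted over the list alone, median 0.15, adjusted p = 0.0154, adjusted p = 0.583 with an estimated correlation), with Rpl12 at 0.43 ± 0.08. Their median was 0.051 and 0.045 with quantile normalization within cell types and over all arrays, and 0.048 with median centring. The calls that held with an estimated correlation were those of the stem cell and S phase lists (adjusted p = 0.0402 each) and of the immediate early and ribosome biogenesis lists (0.0360 each).

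**Figure D2:**
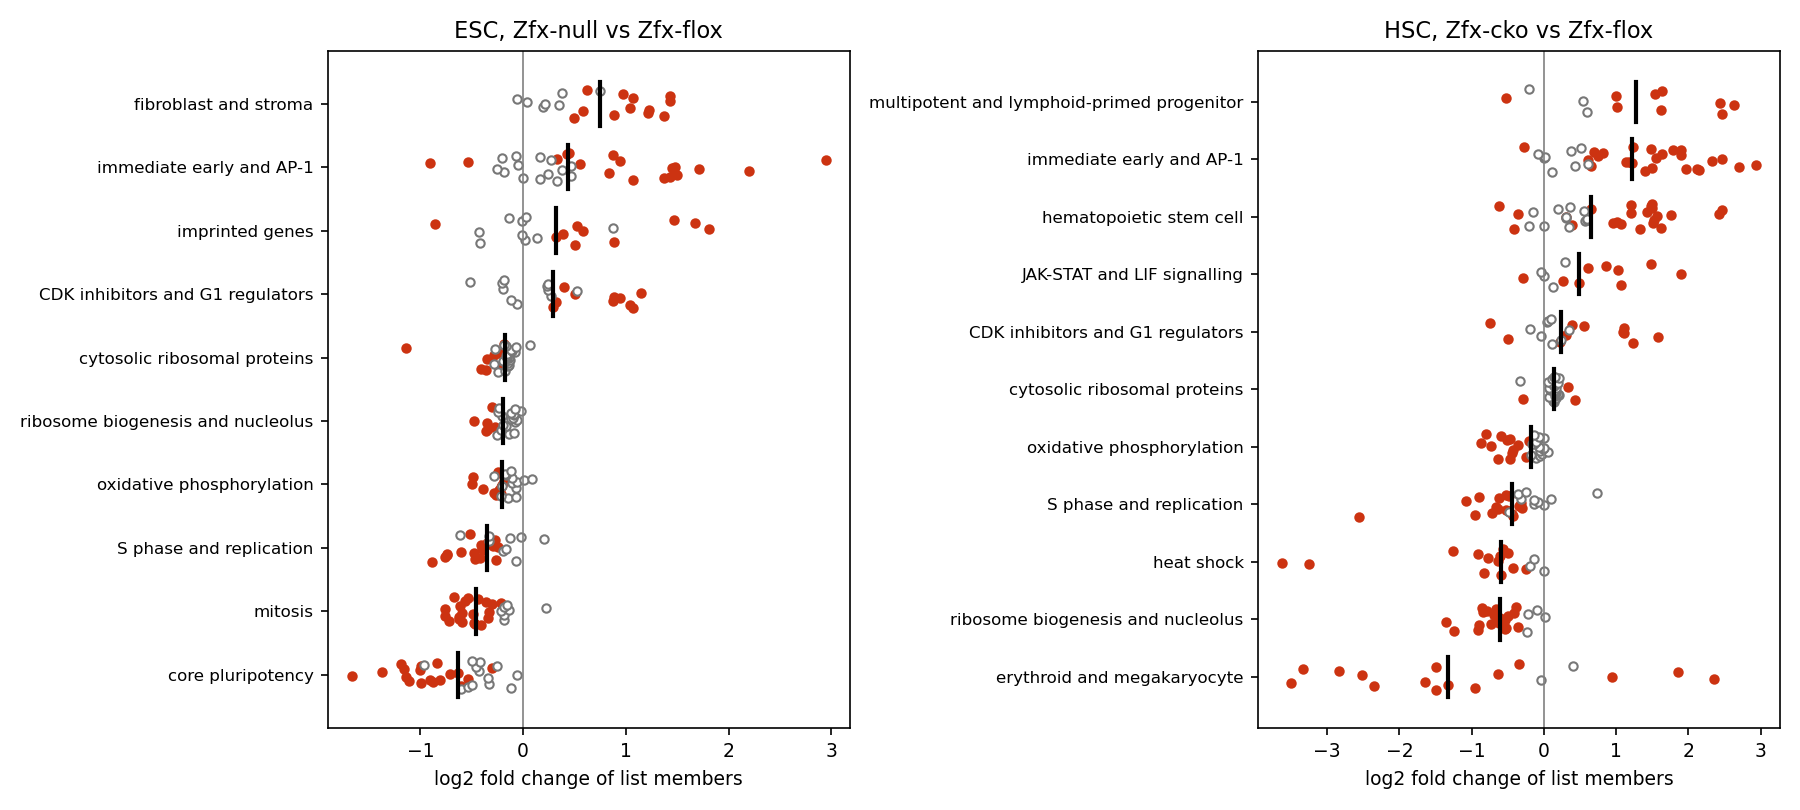
Log2 fold change of the members of each gene list past an adjusted p of 0.05 in ESC (left) and HSC (right), 1 point per tested gene. Filled points passed the threshold, open points did not, and a black bar marks the list's median. The lowest medians are −0.64 for core pluripotency in ESC and −1.32 for erythroid and megakaryocyte genes in HSC.

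The other HSC lists did not pass, and here too counts given once were the same adjusted over the list alone. Markers of cells that a gate can let through moved in part. Of 18 granulocyte and monocyte genes 5 rose and 1 fell (adjusted p = 0.19), with lysozyme Lyz2 at 1.30 ± 0.19. Of 10 B, T and NK genes 4 rose (0.19, Cd79b 1.46 ± 0.26) and of 10 mast cell and eosinophil genes 4 rose (0.19, Fcer1a 1.18 ± 0.21). Endothelial genes had 5 higher and 1 lower of 9 (0.223), with von Willebrand factor, Vwf, at 1.49 ± 0.23 and Plvap at −2.04 ± 0.22. Fibroblast and stroma genes had 4 and 1 of 10 (0.303), with collagen V, Col5a1, at −3.03 ± 0.12. Core pluripotency genes had 3 higher and 3 lower of 13 (0.563), and Tbx3 and Tcl1 were below the filter in HSC. Endoderm genes had 4 higher and 1 lower of 13 (0.268) and trophectoderm genes 3 higher of 7 (0.334). Streak and mesoderm genes had 1 lower of 7 (0 adjusted over the list alone, 0.903). The neuroectoderm list with 4 tested genes (1 higher), the 2-cell and germline list with 3 (1 higher) and the paralog list with Zfp711 alone were too short for a list test.

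Of 23 p53 targets 9 rose and 6 fell in Zfx-cko HSC (adjusted p = 0.334), with the kinase Plk2 at 2.31 ± 0.11 and Zmat3 at −1.31 ± 0.11. Integrated and endoplasmic reticulum stress genes had 7 higher and 7 lower of 29 (7 and 8 adjusted over the list alone, 0.573), with asparagine synthetase, Asns, at −1.40 ± 0.07. Oxidative stress and metallothionein genes had 3 higher and 9 lower of 18 (0.0514), and the metallothioneins Mt1 and Mt2 fell by 2.30 and 1.75. Interferon response genes had 5 higher and 5 lower of 25 (6 and 7 adjusted over the list alone, 0.994), with Rsad2 at 1.45 ± 0.13. Apoptosis regulators had 13 higher and 2 lower of 25 (14 and 3 adjusted over the list alone, 0.0622), with the survival gene Bcl2 from 815 ± 16.6 to 2641 ± 21 (1.68 ± 0.17). Mitosis genes had 5 higher and 7 lower of 28 (5 and 8 adjusted over the list alone, 0.185). Glycolysis and hypoxia genes had 10 and 4 of 22 (11 and 4 adjusted over the list alone, 0.19), with Ndrg1 at 1.38 ± 0.09. Cholesterol biosynthesis genes had 4 and 9 of 18 (5 and 10 adjusted over the list alone, 0.0866). Imprinted genes had 2 higher and 3 lower of 12 (3 and 3 adjusted over the list alone, 0.7) and Y-linked and X-inactivation genes 0 past of 5 (0.994). Notch, Wnt and BMP targets had 5 higher and 1 lower of 14 (0.334), with Notch1 at 1.54 ± 0.09, Id2 at 1.79 ± 0.14 and Hes1 at −0.74 ± 0.15. In the Notch, streak, endoplasmic reticulum stress and Y-linked lists the median, the mean and the test did not share a sign.

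Besides the estimated correlation, the G1 list lost its call without HSC Zfx-flox replicate 1 (adjusted p = 0.0545), with median centring (0.0546), with the stricter filter (0.0506) and without a variance trend (0.0537), within 5.75e-05 to 0.165 over all alternatives. The ribosomal protein list lost it with both quantile normalizations (0.152 and 0.117), median centring (0.287), no variance trend (0.0740), fry (0.0705) and without HSC Zfx-flox replicate 1 (0.122), within 0.000389 to 0.583. With the mean of all probe sets of a gene, the log2 changes of Tlcd4 (−2.88), Cachd1 (−2.21), Sphk1 (−2.12), Marcks (1.75), Asb4 (1.75), Col5a1 (−1.62), Lmna (−1.20), Id2 (1.08), Bcl2 (1.07), Nolc1 (−0.88), Ccng2 (0.74), Mecom (0.72), Gab1 (0.64), Rsad2 (0.59), Orc1 (−0.48) and Notch1 (0.45) were smaller by over 1.5 times and still passed. Fgf13, Asb4, Ccr9, Plk2 and Zfp711 in Zfx-flox and Hpn in Zfx-cko lay below the pseudocount, which sets the size and rank of their change. With the pseudocount at the 10th percentile they were at 3.69, 3.53, 3.05, 3.25, 2.78 and −3.82, and without one Asb4 was at 4.07. Further tested probe sets of Marcks, Lmna, Orc1, Ccng2, Socs3, Bcl2 and Notch1 did not all pass, and none passed in the opposite direction.

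The ESC and HSC effects were set against each other to ask whether loss of Zfx changed the same genes in both stem cell types. Of 11175 genes tested in both, 740 were higher in both cell types and 652 lower in both, while 290 rose in ESC and fell in HSC and 306 did the reverse. Independent lists would share 371, 345, 351 and 365 genes, and two-sided Fisher's exact tests gave odds ratios of 3.54, 3.04, 0.76 and 0.77 (adjusted p = 3.18e-107, 4.47e-79, 7.15e-05 and 0.00013). The cell types share no array, but the joint fit gives each gene the same standard error in both. A gene with a small spread is thus called more easily in both, so independent lists are not the exact expectation. Genes are not independent replicates either, which the Fisher tests take them to be. Across genes, log2 changes correlated at Pearson's r = 0.223 and Spearman's rho = 0.192. Genes higher in both included Zfp711, Ier3, Filip1l (1.69 in ESC and 1.71 in HSC), Procr (1.62 and 2.47) and Ctla2b (1.60 and 1.98). Genes lower in both included Cibar1, Zap70 (−1.96 and −2.08), the serine protease Hpn (−1.73 and −2.67), the sodium pump subunit Atp1b2 (−1.50 and −2.87) and the KDEL receptor Kdelr1 (−1.36 and −1.58). Mt1 (1.39 and −2.30) and the chaperone cofactor Bag2 (1.49 and −1.51) rose in ESC and fell in HSC, and Mcf2 (−1.30 and 2.12) and 1700019D03Rik (−1.35 and 2.02) did the reverse. The test of the difference itself found 3848 of the 11175 genes to change differently, 1913 with a higher and 1935 with a lower change in HSC than in ESC. The HSC contrast also holds Cre, and HSC RNA had an extra amplification round. Neither can be told apart from the cell type in this test.

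**Figure D3:**
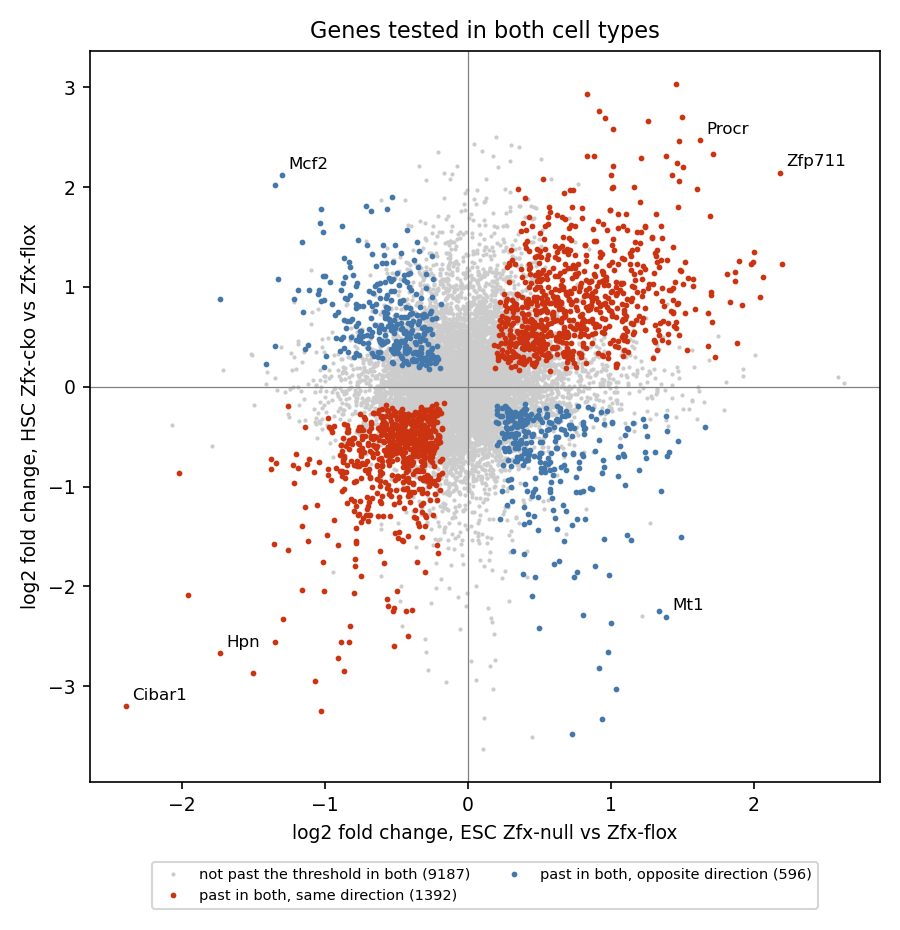
Log2 fold change of each of 11175 genes in HSC (Zfx-cko against Zfx-flox, vertical axis) against ESC (Zfx-null against Zfx-flox, horizontal axis), 1 point per gene. Red points passed the threshold in both cell types in the same direction (1392 genes), blue points in opposite directions (596 genes), and grey points did not pass in both.

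Without a variance trend the shared count in the same direction was 716 and the opposite count 249, the latter 380 with median centring, and 2323 genes differed between cell types. The HSC call of Zap70 was lost without HSC Zfx-flox replicate 1, Zfx-flox replicate 2 or Zfx-cko replicate 2 (adjusted p = 0.111, 0.0592 and 0.121, within 0.00621 to 0.121 over all alternatives). Its log2 change there was −1.23 without HSC Zfx-cko replicate 2 and −0.78 with the mean of all its probe sets. That mean gave −0.99 in ESC and −1.42 in HSC for Atp1b2 and 0.83 in HSC for 1700019D03Rik, which still passed.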

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

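The tests of array scaling, of 5′ to 3′ signal, of heat shock genes and of cross-hybridization were chosen only after the result was seen. The remaining tests of explanations below were set beforehand. The standard errors of medians over genes given below come from a bootstrap over those genes. Genes are not replicates, so these standard errors do not measure the spread between arrays.

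In Zfx-cko HSC, erythroid and megakaryocyte genes had a median log2 change of −1.32, with 12 of 17 tested genes lower. Array scaling as the whole cause was argued against by quantile normalization, which left the median at −1.43 while the median of all tested probe sets shifted by 0.09. Weaker 5′ signal as the whole cause was argued against by the Gapdh control ratio, which differed by −0.32 in Zfx-cko (SD 0.21). Other controls fell more at 5′, such as AFFX-PheX (−0.54 at 5′ and −0.10 at 3′), still by less than the list's median. More mature erythroid cells in the Zfx-flox sort, which a lineage depletion would remove, may have contributed. The 3 tested transcripts taken beforehand as mature erythroid were Hemgn (−1.44), Hbb-b2 (−0.61) and Hba-a2 (0.37), of which Hemgn alone passed. Whether Hemgn marks mature cells only was not checked. Their median lay above the list's by 0.71, with a standard error of 0.82, so such a contribution cannot be told apart. A beta-globin probe set shared by 4 genes read 448 ± 12.3 and 180.3 ± 14.8 but did not pass in the joint fit (log2 change −1.25, adjusted p = 0.144), and 2 alpha-globin ones changed by −0.69 and −1.14 (adjusted p = 0.00405 and 0.00903). Other differences in the mix of stem and progenitor cells within the sort gate stayed open and untested. So did the difference in Zfx genotype and the Cre that goes with it.

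Immediate early and AP-1 genes rose in Zfx-cko HSC with a median log2 change of 1.23. Handling stress of the kind that raises heat shock genes together with them was argued against by the heat shock list, whose median was −0.60 with a standard error of 0.10, and by Hspa1a and Hspa1b, which both fell. More granulocytes or monocytes in the Zfx-cko sort, which the lineage-negative gate would remove, could not be told apart, because the median of 5 tested abundant transcripts was −0.0608 with a standard error of 0.35. Lyz2 rose by 1.30 while Ngp, S100a8, Csf1r and Ltf did not pass (−0.06, −0.09, 0.27 and −0.39). Other handling differences, a different mix of stem and progenitor cells within the gate, and the difference in genotype with its Cre stayed open and untested.

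In Zfx-null ESC, 5 Zfx probe sets rose while 1 fell to the floor. Array scaling was argued against by quantile normalization, under which the median rise was 1.55 while the median of all tested probe sets shifted by 0.01. Cross-hybridization to the rising paralog Zfp711 as the common cause was argued against by HSC, where Zfp711 rose about as much, by 2.14 ± 0.27, but the 4 of these probe sets tested had a median log2 change of 0.0735 (largest standard error 0.21), against 1.43 in ESC. The remaining probe set that rose in ESC, 1449512_a_at, was below the filter in HSC. It read 7.14 ± 3.98 there in Zfx-flox and 21.9 ± 4.28 in Zfx-cko (log2 change 0.77 ± 0.26, not tested), near the floor but in the direction of a rise. For this probe set and 1425972_a_at, the 1 of the 4 that rose in HSC too, signals of different probe sets are not comparable, so a contribution of Zfp711 cannot be told apart. More RNA from the mutated Zfx locus is a biological alternative that was not tested.

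The HSC and ESC effects differed by the test of the difference for 3848 of 11175 genes in limma. Cre in HSC Zfx-cko and the extra amplification round of HSC RNA cannot be told apart from the cell type here. At the preset correlation 8 lists passed in this test, and none passed with an estimated correlation, where the lowest adjusted p was 0.152. The latter version again refers to 4 residual degrees of freedom. For these lists, the difference of HSC and ESC log2 changes had a median of 0.33 for cytosolic ribosomal proteins (camera adjusted p = 1.48e-05), −0.52 for heat shock (6.72e-05), −0.42 for ribosome biogenesis (6.72e-05), 0.40 for mitosis (9.16e-05), 0.79 for immediate early genes (0.00397), −1.08 for erythroid and megakaryocyte genes (0.0061), 0.58 for hematopoietic stem cell genes (0.00612) and 0.49 for JAK-STAT and LIF signalling (0.0412). For the ribosomal protein list this median was 0.10 with both quantile normalizations and 0.21 with median centring (adjusted p = 0.00704, 0.00713 and 0.00125), and JAK-STAT and LIF signalling did not pass with quantile normalization over all arrays (adjusted p = 0.0503). Single genes with the largest difference toward HSC were Mcf2 (3.42), 1700019D03Rik (3.36), N4bp3 (2.81), Tmem191c (2.68) and Myo1f (2.61). Those with the largest difference toward ESC were Sphk1 (−4.27), Lmna (−4.21), Col5a1 (−4.07), Ermap (−3.95) and Myh10 (−3.73). This ranking holds for the probe set with the highest mean of each gene. With the mean of all probe sets the differences were 3.42, 2.09, 2.81, 1.87 and 2.35 for the former and −2.73, −1.75, −2.78, −3.95 and −1.89 for the latter, with Sphk1 then below the filter.

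Control probe sets outside the tests also differed between groups by more than the arrays' spread. The beta-actin controls were higher in Zfx-null ESC, with log2 ratios of group means of 0.34 (3′), 0.43 (5′) and 0.48 (middle). There the 18S ribosomal RNA controls were lower, at −0.26 (3′), −0.26 (5′) and −0.45 (middle), as were the transferrin receptor 3′ control (−0.68) and 1 of 2 B2 repeat controls (−0.31). In Zfx-cko HSC the B1 and this B2 control were higher by 0.49 and 0.33, and the other B2 control by 0.10. The 18S controls were lower there, at −0.55 (3′), −0.13 (5′) and −1.20 (middle, 1941 ± 12.5 to 847 ± 15.8), and the transferrin receptor 3′ control at −1.48. Controls of bacterial sequence shifted too. AFFX-BioC-5_at changed by 0.34 in HSC (903 ± 72.8 to 1146 ± 16.2) and by −0.36 in ESC (727 ± 122 to 568 ± 45.4), and AFFX-LysX-M_at by −0.41 in HSC (1189 ± 38.9 to 894 ± 14.9). Shifts of some size therefore occurred where no mouse RNA is read.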

How the results depend on the processing

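Each setting was planned. Named gene and list results are counted first: of 174 named-gene calls, 155 kept direction and threshold under every alternative, 17 lost the threshold under some other setting and 7 without some array, and 0 changed sign; of 21 list calls 8 held under every alternative, and 13 were lost under some setting, all with an estimated correlation. With the mean of all probe sets of a gene, 10 ESC and 22 HSC named-gene values moved by over 1.5 times, 9 and 22 of them toward 0, and 9 and 21 still passed. No shared gene call had the opposite sign in any setting compared. Where an array was left out, its group kept 1 array, which is assumed to vary like the others. Without a variance trend, 4156 probe sets passed in ESC in place of 6528, 933 genes were lower in place of 1771, 2323 differed between cell types in place of 3848, and 716 and 249 genes were shared in the same and in opposite directions in place of 1392 and 596. With median centring, 1162 genes were lower in ESC and 380 changed in opposite directions. A minimum change of 2-fold left 1237 probe sets in ESC and 2615 in HSC, and 494 higher and 172 lower genes in ESC and 857 and 439 in HSC; here the stricter criterion itself is the cause. The correlation of log2 changes of 0.223 was 0.212 with the lower pseudocount, 0.206 without one, 0.231 and 0.232 with quantile normalization within cell types and over all arrays, 0.159 without a filter and 0.265 with the stricter one. Lists past the threshold numbered 4 in ESC and 4 in HSC with an estimated correlation, in place of 10 and 11, and 22 and 25 with fry, which asks another question. The version with an estimated correlation also refers to 4 residual degrees of freedom. Leaving out each array in turn gave 4292 to 6007 probe sets in ESC and 7228 to 10038 in HSC. It gave 1310 to 1775 higher and 1046 to 1611 lower genes in ESC, 2017 to 2815 and 1799 to 2440 in HSC, 2942 to 3447 genes that differed, 1040 to 1107 and 410 to 476 shared in the same and in opposite directions, a correlation of 0.211 to 0.222, and 10 to 11 lists in ESC and 9 to 13 in HSC. The lowest ESC counts came without ESC Zfx-flox replicate 1 (4292 probe sets, 1046 lower genes) and Zfx-null replicate 1 (4299 probe sets), and 1112 lower genes without ESC Zfx-flox replicate 2. Signs changed only for values that had not passed the threshold. In HSC, 1428046_a_at of Zfx gave −0.0262, −0.0275 and −0.0473 and 1428047_s_at −0.0280, −0.0291 and −0.000704 with quantile normalization within cell types, over all arrays and median centring. Leaving out an array gave −0.0578 to 0.158 and −0.0707 to 0.264 for these, −0.254 to 0.246 for 1439404_x_at (−0.400 to 0.16 in ESC), −1.39 to 0.60 for Ltf, −0.24 to 0.11 for Ngp and −0.40 to 0.21 for S100a8, none of them past the threshold. Except for the added criteria and the arrays left out, the cause was not tested. The labels do not say that replicate numbers pair the arrays, and 2 pairs per cell type do not settle it (correlation of deviations 0.319 in ESC and 0.0716 in HSC); with the replicate block 4371 genes passed in ESC, 3605 of them among the 3665, and 5781 in HSC, 5116 of them among the 5199. Signal over background was not measured. The 69.4% to 78.9% of probe sets per array above the pseudocount follow from its choice as the 25th percentile of these same values.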

Other observations

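The test of whole chromosomes was set beforehand. The grouping of genes by the start of their symbol and its test were chosen only after the result was seen.

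Beyond the lists, genes were grouped by the letters their symbols start with. In Zfx-cko HSC 14 of 148 such families passed at the preset correlation and none with an estimated one, where the lowest adjusted p was 0.456. The latter version refers to 4 residual degrees of freedom and can hardly pass any of so many families. Its outcome therefore does not decide whether these families changed. Mitochondrial ribosomal protein genes were lower, with 33 of 47 Mrpl genes down and 1 up (median log2 change −0.52, camera adjusted p = 3.37e-09) and 24 of 29 Mrps genes down (−0.45, 3.21e-08). Proteasome genes were lower too, 12 of 14 Psmd genes (−0.65, 3.06e-06) and 6 of 10 Psmb genes (−0.36, 0.00478). So were 13 of 18 Nup genes of the nuclear pore (−0.42, 5.63e-05), 25 of 46 Eif translation initiation genes, with 3 up (−0.30, 0.000202), 10 of 14 Timm genes of mitochondrial protein import (−0.45, 0.000407) and 9 of 11 Utp genes of ribosome assembly (−0.49, 0.000837). Zinc finger genes named Zfp were more often higher, 100 of 286 with 17 lower (0.28, 0.00255), as were surface antigens named Cd, 25 of 59 with 6 lower (0.39, 0.0164). These medians kept their sign under each scaling tried, but those of Zfp and Cd were as low as 0.17 and 0.24, and 70 to 77 Zfp genes were higher under the other scalings.

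In Zfx-null ESC 11 of 154 families passed at the preset correlation and none with an estimated one, where the lowest adjusted p was 0.688. The same limit of the latter version applies here. The grouping gave lower Mrpl genes (18 of 47 down; median −0.22, camera adjusted p = 0.000889), Mrps genes (14 of 29 down and 1 up; −0.26, 0.00285) and small nucleolar RNA host genes named Snhg (9 of 14 down and 1 up; −0.34, 0.00285). Collagen genes were higher (15 of 31 up and 1 down; 0.57, 0.00218), as were the matrix proteases named Adamts (6 of 11 up; 1.30, 0.00777). These medians kept their sign under each scaling tried. With median centring the lower genes numbered 6 Mrpl, 7 Mrps and 6 Snhg.

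A hypothesis was that gain or loss of a whole chromosome in the Zfx-null ESC could account for many of its changes. With genes placed on chromosomes by the GRCm38.p6 table, the largest departure of a chromosome's median log2 change from that of the other genes was 0.0927, for chromosome 18, which argues against a whole-chromosome change in all cells. On chromosome 3, changes of at least 2-fold were more frequent than elsewhere in both cell types, with odds ratios of 1.78 in ESC (two-sided Fisher's exact test, adjusted p = 0.00579) and 1.57 in HSC (adjusted p = 0.00461), a pattern noticed after the values were seen and not explained. In ESC chromosome 1 (odds ratio 1.5, adjusted p = 0.04997) and, with fewer such changes, chromosome 11 (0.60, adjusted p = 0.0294) also passed.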
